A study of Mus musculus with 8 samples.

How the data were processed

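The series holds 8 chromatin immunoprecipitation libraries from Ba/F3 and HPC7 cells that stably express triple-FLAG murine MYSM1. Per the labels' protocols, cells were fixed with 1% formaldehyde for 10 min, chromatin was sheared to about 250 bp, and antibodies to FLAG, H2AK119ub or H3K27ac were used, with an input library for each line. Per the submitters' processing notes, the tools were Bowtie 1.0.0 and MACS 1.4.1 and the genome build was mm9. Their thresholds, the treatment of reads that align to several places, the control used for each call, and whether the lines were pooled are not given in the sources used here. These settings bear on the measurements, since an aligner that keeps reads with several placements can raise peaks in repeats, and an aligner that drops them can hide such peaks.

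The authors deposited 1 list of MYSM1-FLAG peak summits with 4 columns (chromosome, start, end and peak name) and no header. Start equals end on all 2099 lines, so each line was read as 1 position on mm9; whether positions count from 0 or 1 is not stated, which moves a distance by 1 bp. The deposited list holds no score and no label of the cell line, so the planned overlap between lines, the planned test of scores at gene lists and each planned threshold on the score were not run. The peak names carry a running number, which was not used as a measure of strength. The H2AK119ub, H3K27ac and input libraries were not analysed here. With 1 library per group there is no replicate error, and every test below compares positions within the list with other positions or genes.

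Positions were joined to the NCBIM37 genome, which is mm9, and the GENCODE M1 annotation. The build was checked by moving the summits: 147 lay within 1 kb of an annotated TSS, against 82 to 98 after moves of 10 kb, 100 kb or 1 Mb in either direction, and 72 lay within 200 bp against 15 and 16 after moves of 10 kb. A promoter summit lies within 1 kb of the TSS of any transcript. Random placement moved each summit to a place within 1 Mb on the same chromosome, in 1000 draws (200 for exons, introns and intergenic sequence). Spacing was compared with 1000 uniform placements between the first and last summit of each chromosome, and chromosome totals with 10000 draws in proportion to chromosome length. Chromosome lengths included assembly gaps.

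Gene lists and motif consensus sequences were fixed before the data were examined, and they were matched to 22225 protein-coding gene symbols, older symbols through a RefSeq table. The 14 lists were tested with two-sided Fisher's exact tests on genes with a promoter summit, with Benjamini-Hochberg adjustment over the lists. The comparison of ribosomal protein genes with 4 other lists and with the rest of the genes was added later and adjusted over 5 tests. The 14 consensus sequences were sought on both strands within 50 bp of a summit and compared with the same positions moved by 1000 bp and with the reversed consensus (McNemar exact tests, adjusted over the consensus sequences).

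Repeat groups were defined after the sequences were seen. A summit belongs to the dispersed family when the first 12 bases of AACAAGGGAGATATA, on either strand, lie within 100 bp, and otherwise to the tandem group when 4 perfect units of AAAGG do. Perfect tandem arrays of units of 2 to 6 bases and at least 40 bp were listed across the genome, loci within 200 bp of each other were joined, and units with at least 200 loci were compared. Copy number is the median number of times that the 31-base words of a 201 bp window occur in the genome, and a window with a median of 1 is called unique.

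Genes and sites are named by a rule fixed before the data were examined: the first and last summit of the 3 chromosomes with most summits, the 5 densest clusters within 10 kb, the genes at those sites, up to 20 ribosomal protein genes with a promoter summit and 3 genes of each other list in genome order, Mysm1 and Trp53. Some genes that this rule names are not reported here. Each result was also computed with other settings chosen before the data were examined: the promoter window (500 bp, 2 kb, 5 kb), protein-coding TSSs alone, a background of genes with a CpG-rich promoter (observed over expected above 0.6 within 500 bp of a TSS), the cluster distance, summits within 250 bp counted once, autosomes alone, and the motif window. Leaving out both repeat groups, and motifs at promoter summits alone, were added after the data had been examined.

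The tests were run on simulated data first. In 20 simulated lists without an effect, the promoter test called 1 and the ribosomal protein, chromosome and spacing tests called 0. In 20 simulated lists with 100 planted promoter summits, 40 of them at ribosomal protein genes, the ribosomal protein list was called in all 20, no other list was called, and 100% of the planted genes were found among 22225 genes. The planted summits were placed inside the promoter window, so their recovery was fixed in advance. A motif planted at 5% of the summits was called in 20 of 20 simulations. These used random bases for summits and flanks, so they do not test false calls in repeats. The analysis used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6, numba 0.67.0, matplotlib 3.10.9 and samtools 1.23.1.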

Results

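The study asked where MYSM1, a deubiquitinase that acts on histone H2A, sits on the genome of mouse blood progenitors. Chromatin was immunoprecipitated from 2 cell lines that stably express murine MYSM1 with a triple FLAG tag: Ba/F3, a pro-B line that grows in interleukin 3, and HPC7, a multipotent progenitor line that grows in stem cell factor. Each line gave 1 MYSM1-FLAG library, 1 input library, 1 H2AK119ub library and 1 H3K27ac library, so the 8 libraries form 8 groups of 1 and nothing could be tested against replicates. The data analysed here are the deposited list of 2099 MYSM1-FLAG peak summits on mm9, which covers 21 chromosomes. The list gives a position for each summit but no height, score or p-value, and it does not say in which line a summit was called, so Ba/F3 and HPC7 could not be compared. Read depth is not given in the sources used here, and the intervals below are exact 95% Clopper-Pearson intervals that cover counting error only.

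The promoters of cytosolic ribosomal protein genes, which encode the protein part of the cytoplasmic ribosome, carried summits far more often than other promoters. Of 78 such genes, 40 had a summit within 1 kb of a transcription start site (TSS), a share of 51.3% (interval 39.7% to 62.8%), against 86 of the 22147 other protein-coding genes, or 0.388%. The odds ratio was 270 (two-sided Fisher's exact test, p = 3.12e-71, adjusted p = 4.36e-70 over 14 gene lists). Both ribosomal subunits were represented: 14 of 32 genes of the small subunit (43.8%) and 26 of 46 genes of the large subunit (56.5%) had a summit, and these shares did not differ detectably (Fisher's exact test, p = 0.358). The title of the series names ribosomal protein genes, so this list is not independent evidence of its direction.

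**Figure D1:**
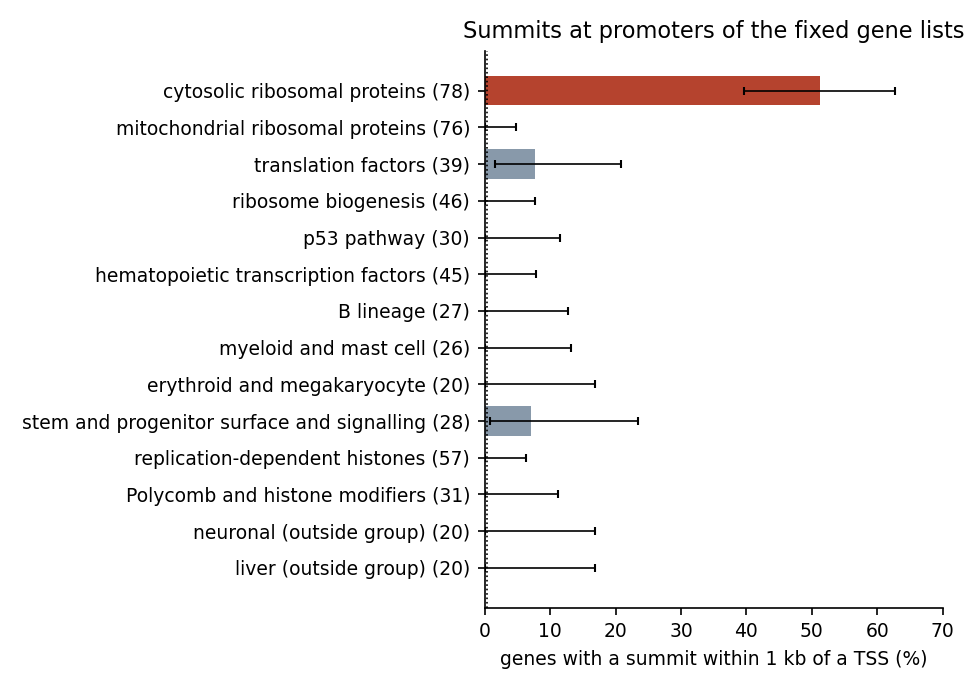
Bars give the percentage of genes in each fixed list with a MYSM1-FLAG summit within 1 kb of a TSS, with the number of genes in brackets, exact 95% intervals as black lines and the share of genes outside the ribosomal protein list as a dotted line. The cytosolic ribosomal protein genes reach 51.3%, translation factors 7.69% and stem and progenitor genes 7.14%, and the remaining lists are at 0.

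The summits lay at the 5' ends of these genes. In Rpl32 on chromosome 6 (ENSMUSG00000057841.3, 115755523 to 115758765, minus strand) the summit was at position 115758683, 82 bp inside the gene in an intron. In Rps6 on chromosome 4 (86500564 to 86503316, minus strand) it was at 86503088, in an exon and 148 bp downstream of the nearest TSS. Rpl11 and Rpl5, whose proteins bind MDM2 and thereby stabilise p53, had summits on chromosome 4 at 135609192 and on chromosome 5 at 108329750, both in introns. The summit of Rpl35 on chromosome 2 at 38860556 was in an exon, 7 bp downstream of a TSS. Summits were also present within 300 bp of a TSS of Rpl7, Rpl31, Rpl37a, Rpl7a, Rpl12, Rps3a, Rpl34, Rpl9, Rpl6, Rpl18, Rps3, Rps15a and Rpl13. Across the 40 summits of the list, the median position was 83 bp downstream of the nearest TSS (interquartile range 41.8 to 128 bp), 34 lay downstream of it, and 39 lay within 250 bp of it. By the annotation, 22 fell in an exon and 18 in an intron. No summit was found at 38 genes of the list, among them Rpl3, Rpl4, Rpl10, Rps19 and Rplp0, which were chosen as examples after the values were seen.

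**Figure D2:**
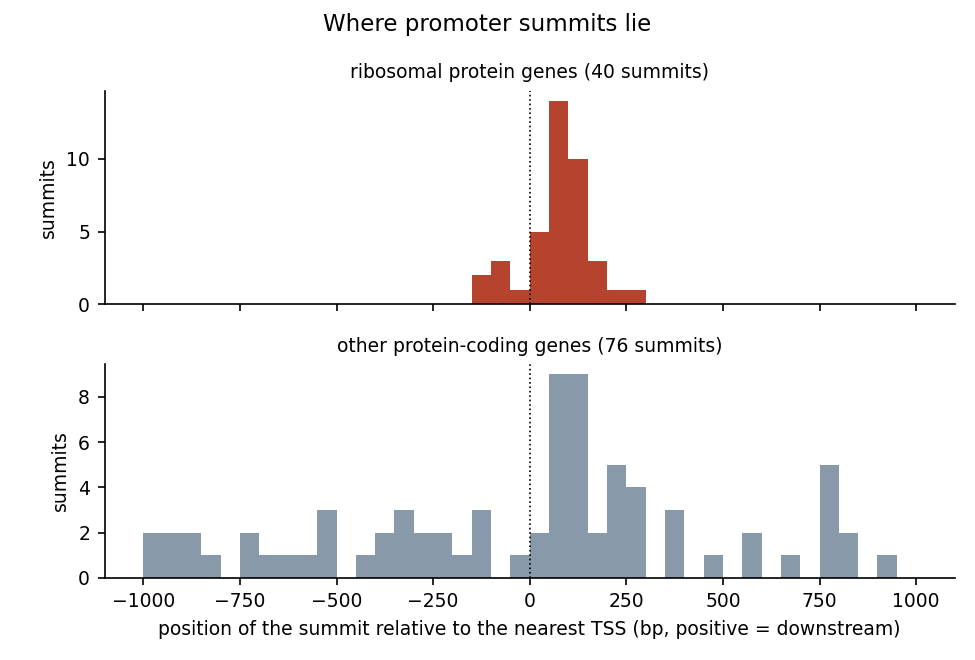
Histograms in 50 bp bins of the position of each promoter summit relative to the nearest TSS of a protein-coding gene, in bp with positive values downstream, for summits of cytosolic ribosomal protein genes (top) and of other protein-coding genes (bottom). The 40 summits of the ribosomal protein genes have a median of 83 bp and run from -143 to 295 bp, while the 76 others run from -988 to 908 bp.

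Among 39 translation factors, 3 had a promoter summit (7.69%, interval 1.62% to 20.9%), which was above the share of other genes (odds ratio 14.9, Fisher's exact test, adjusted p = 0.00981) and below the share of ribosomal protein genes (Fisher's exact test, adjusted p = 1.7e-06). The 3 genes were Eef2, the elongation factor that moves the ribosome along the message, with a summit 121 bp downstream of its TSS on chromosome 10, Eif3d, a subunit of an initiation factor, at 125 bp on chromosome 15, and Eef1g, a subunit of an elongation factor, at 243 bp on chromosome 19. With a promoter window of 5 kb the call for translation factors was lost (Fisher's exact test, adjusted p = 0.0959). None of 76 mitochondrial ribosomal protein genes had a summit, which allows a share of up to 4.74%. None of 46 ribosome biogenesis genes had one, which allows up to 7.71%. Outside either list about 0.57% of genes had one, so these counts of 0 lie near the background.

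Lists of blood lineage and p53 response genes were not called for promoter summits. Outside each list with a count of 0, about 0.57% of genes had a promoter summit. In lists of this size a count of 0 therefore does not separate them from other genes. No summit lay at the promoter of 45 hematopoietic transcription factors, 27 B lineage genes, 26 myeloid and mast cell genes, 20 erythroid and megakaryocyte genes or 30 p53 pathway genes, and the upper bounds of these shares were 7.87%, 12.8%, 13.2%, 16.8% and 11.6%. The counts were also 0 for 57 replication-dependent histone genes, 31 genes of Polycomb and other histone modifiers, 20 neuronal genes and 20 liver genes. Among 28 genes of stem and progenitor surface receptors and signalling, 2 had a summit, a share of 7.14% against 0.559% of other genes. The odds ratio was 13.7, and the list was not called (adjusted p = 0.0511, Fisher's exact test). The genes with a summit were Kit, the receptor for stem cell factor, and Cish, a feedback inhibitor of cytokine signalling. In Kit the summit at 76041114 on chromosome 5 lies in an intron of the gene and 608 bp upstream of an internal TSS. The summit of Cish lies 654 bp upstream of the gene on chromosome 9. Both lie in repeated sequence, and without the summits of the repeat groups described below no gene of this list had one. Mysm1 itself (chromosome 4, 94608731 to 94645791) held no summit, and the nearest was 707203 bp from its TSS. Trp53, the gene of p53 (chromosome 11, 69393861 to 69405375), held none either, and the nearest was 391861 bp away.

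Most summits were away from promoters. Of the 2099 summits, 147 (7.0%, interval 5.95% to 8.18%) lay within 1 kb of a TSS, against a mean of 4.23% and a highest value of 5.48% in 1000 draws that moved each summit to a random place within 1 Mb (two-sided permutation of positions, p = 0.002, the smallest these draws can give). Another 7 summits were in exons (0.333%), 598 in introns (28.5%) and 1347 between genes (64.2%). In 200 such draws the random means were 2.37% for exons, 34.5% for introns and 58.9% for intergenic sequence, and each share differed from them (two-sided permutation of positions, p = 0.01, the smallest these draws can give).

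The summits away from promoters fell largely into a pair of repeat groups, which were found in the summit sequences after the list had been examined. The first group holds 932 summits (44.4%, interval 42.3% to 46.6%) at a dispersed repeat with the sequence unit AACAAGGGAGATATA, and 0 of 2099 random places had its first 12 bases. The second holds 603 summits (28.7%, interval 26.8% to 30.7%) at tandem repeats of AAAGG, found at 1 random place. The remaining 564 summits include all 40 at ribosomal protein promoters. They are not free of other repeats: 65.2% lay in unique windows, and 85 had a copy number over 100. Of these 564, 103 (18.3%, interval 15.2% to 21.7%) were within 1 kb of a TSS, against a random mean of 5.37% (two-sided permutation of positions, p = 0.002), while 44 of the 1535 summits in the repeat groups were (2.87%, random mean 3.82%, p = 0.07). Of 2685 perfect AAAGG arrays of at least 40 bp in the genome, 592 had a summit within 100 bp (22.0%, interval 20.5% to 23.7%), and the share rose from 6.24% of arrays of 40 to 59 bp to 46.8% of arrays of 100 to 149 bp. Of 1989 copies of the dispersed repeat, 928 had a summit (46.7%), from 1.61% of copies with 1 unit to 85.3% of copies with 4 or more.

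**Figure D3:**
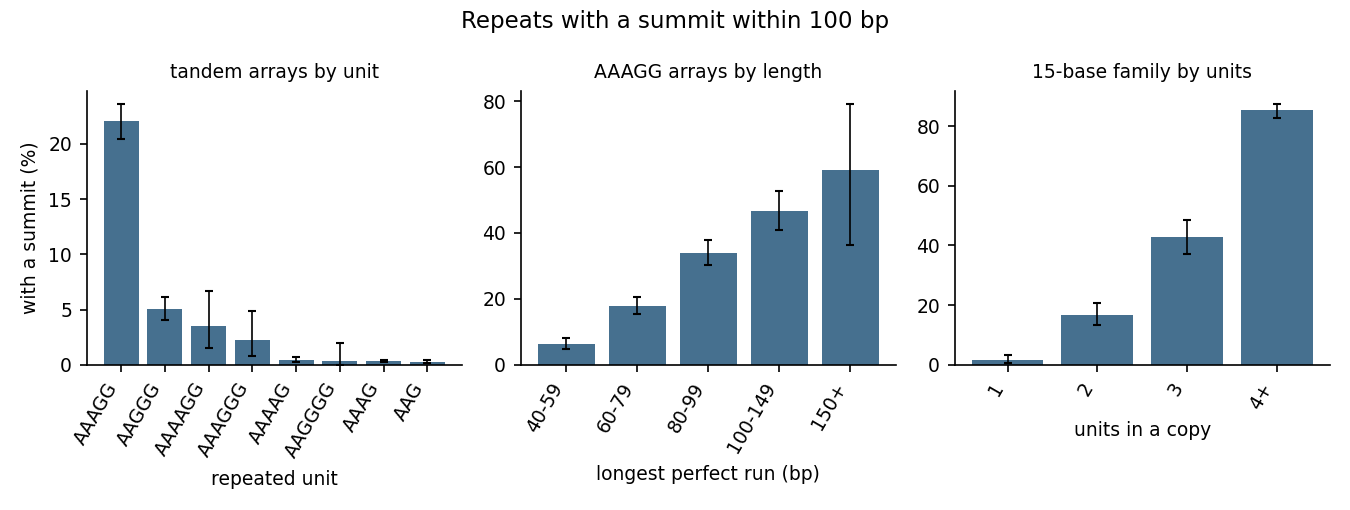
Percentage of repeats in mm9 with a summit within 100 bp, with exact 95% intervals: tandem arrays of at least 40 bp by their repeated unit (left, the 8 units with the highest shares), AAAGG arrays by the length of their longest perfect run in bp (middle), and copies of the dispersed repeat by the number of 15-base units (right). AAAGG arrays stand at 22.0% and AAGGG arrays at 5.02%, and the shares rise to 59.1% of the longest AAAGG arrays and to 85.3% of copies with 4 or more units.

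Summits lay close to one another more often than evenly placed ones. In the list, 668 summits (31.8%) had another within 10 kb, against a mean of 1.69% and a highest value of 3.05% in 1000 uniform draws (permutation of positions, p = 0.001, the smallest these draws can give). Of 343 pairs of neighbours within 10 kb, 297 (86.6%) were 2000 to 3000 bp apart, with a median of 2537 bp, and in 291 of them both summits belonged to the dispersed repeat. Without both repeat groups the share with a neighbour was 3.55%, against a mean of 0.565% and a highest value of 3.01% in the draws for these 564 summits (permutation of positions, p = 0.001). The 3 densest clusters held 4 summits each, on chromosome 1 from 147374811 to 147382851, on chromosome 13 from 15923902 to 15935665 and on chromosome 19 from 48816189 to 48821277. The first and the second of these lie outside annotated genes, and the cluster on chromosome 19 lies in Sorcs3, a gene of a sorting receptor. Another 12 clusters held 3 summits each, of which the first 2 in genome order were on chromosome 1 from 181321219 to 181323686 in Smyd3, a lysine methyltransferase gene, and on chromosome 2 from 148567643 to 148573137 outside genes. All summits of the clusters on chromosomes 1 and 13 belong to the dispersed repeat, as do 2 of 4 in Sorcs3 and 2 of 3 on chromosome 2. Neighbours at most 10 kb apart were joined, so a cluster can span more than 10 kb.

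**Figure D4:**
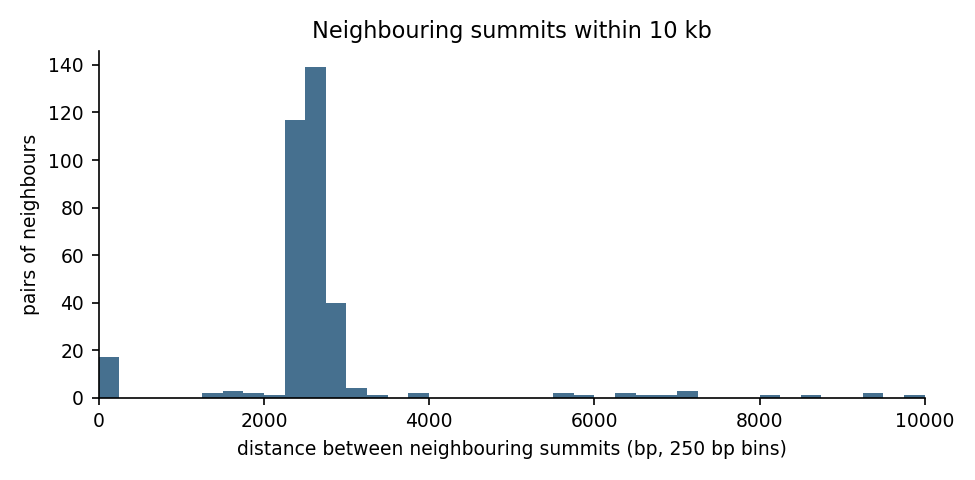
Number of pairs of neighbouring summits by the distance between them in bp, in 250 bp bins up to 10 kb. Of the 343 pairs, 297 lie between 2000 and 3000 bp.

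Chromosomes differed in their number of summits relative to their length (Monte Carlo chi-square test, p = 0.0001, the smallest that 10000 draws can give). Chromosome 17 held 107 summits, 1.42 times the number expected from its length, chromosome 1 held 215 (1.38 times) and chromosome 2 held 184 (1.28 times), each with an adjusted exact binomial p of at most 0.00517. Chromosome 3 held fewer than expected, 96 summits or 0.761 times (adjusted exact binomial p = 0.0264), as did chromosome Y with 4 (0.318 times, adjusted exact binomial p = 0.0424). The expected numbers took no account of assembly gaps or of chromosome copy number in the lines. The low count on Y therefore cannot be read as a deficit in sequence that reads can reach. Without the repeat groups the calls for chromosomes 1, 3 and Y were lost, at 1.24, 0.619 and 0.888 times the expected number (adjusted exact binomial p = 0.324, 0.109 and 1). The first and last sites are named for the 3 chromosomes with most summits. On chromosome 1 the first, at 4275559, lay between genes in the tandem group. The last, at 193212161, lay at the dispersed repeat in an intron of the phosphatase subunit gene Ppp2r5a. On chromosome 2 the first and last were at 4985408, 311 bp from the TSS of Optn, a gene of an autophagy receptor, and at 179002414 between genes. On chromosome 6 they were at 5653048 and 149146550, both between genes and the latter in the tandem group.

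Several consensus sequences of transcription factors were rarer at the summits than beside them, but within 50 bp none was detectably rarer than its reversed sequence. A GATA consensus lay within 50 bp of 124 summits (5.91%), against 286 and 300 of the same positions moved by 1000 bp up and down (McNemar exact test, adjusted p = 3.38e-16). RUNX, E-box, MYB, NFY and YY1 were also lower than in the flanks (McNemar exact test, adjusted p at most 0.0293), and ETS, PU.1, NRF1, SP1, CRE, AP-1 and CTCF were not called. Against the reversed consensus, GATA, RUNX, NFY and YY1 did not differ detectably (McNemar exact test, adjusted p = 0.432, 1, 1 and 0.146), while MYB was found at 199 summits against 123 for its reversed sequence and E-box at 14 against 1 (McNemar exact test, adjusted p = 3.96e-05 and 0.00684). Within 100 bp GATA and NFY were rarer than their reversed sequences as well (McNemar exact test, adjusted p = 0.00367 and 0.0412). Among the 564 summits outside the repeat groups, GATA was at 7.98% against a flank mean of 12.1%, RUNX at 0.709% against 3.19%, E-box at 1.42% against 3.72% and YY1 at 0.709% against 1.33%, all lower and not called (McNemar exact test, adjusted p = 0.163, 0.137, 0.216 and 0.854). In all 2099 summits the same shares were 5.91% against 14.0%, 0.619% against 2.36%, 0.667% against 3.45% and 0.286% against 0.929%. In the 564 summits MYB (12.8% against 21.3%) and NFY (6.03% against 15.5%) stayed called lower (McNemar exact test, adjusted p = 0.0144 and 6.53e-06). SP1 was called higher there, at 26 against 4 and 7 in the flanks (McNemar exact test, adjusted p = 0.00615), with its reversed sequence at 22. The call for YY1 was also lost within 25 bp (McNemar exact test, adjusted p = 0.314). Within 100 bp PU.1 and AP-1 were called lower as well (McNemar exact test, adjusted p = 0.0331 and 0.0279). The polypyrimidine initiator consensus YYCTTTYY was at 1028 summits (49.0%) against 414 and 410 (McNemar exact test, adjusted p = 6.72e-79), but its reversed sequence was found at 1030. AAAGG arrays match both by their sequence, so the reversed sequence cannot separate the consensus from base composition or from these repeats. In the 564 summits the consensus was at 218 against 93 and 99 (McNemar exact test, adjusted p = 1.95e-14), and its reversed sequence at 218. At the 147 promoter summits, a subset added after the data were seen, SP1 was found at 24 (16.3%) against 2 and 5 in the flanks (McNemar exact test, adjusted p = 0.00765), and its reversed sequence at 21. The initiator consensus was called there too, at 43 (29.3%) against 21 and 21 (McNemar exact test, adjusted p = 0.0319), with its reversed sequence at 43.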

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

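The alternatives that leave out both repeat groups or take promoter summits alone were chosen after the data were seen. The share of summits at promoters stayed above its random draws with windows of 500 bp, 2 kb and 5 kb (5.00%, 11.9% and 19.8%), with protein-coding TSSs alone (5.53%) and without the repeat groups (18.3%). The ribosomal protein list was called in each of its alternatives, with shares of 50.6% to 51.3%. Clustering and unequal chromosome totals were called in each of their alternatives. Without the repeat groups the list fell from 2099 to 564 summits, by construction. The number of gene lists called was 2, and 1 with a 5 kb window, where more of the other genes had a summit. The number of consensus sequences called was 7, and it was 4 without the repeat groups and 2 at promoter summits, where fewer summits were tested. Of lists that were not called, the direction reversed for stem and progenitor genes with a 500 bp window (0%) and without the repeat groups (0%), and with a 5 kb window for myeloid and mast cell genes (3.85%), erythroid and megakaryocyte genes (10%) and Polycomb and other histone modifiers (6.45%). Each of these rests on at most 2 genes. Among the other values of single lists and motifs, 99 stayed on their side of the threshold, some uncalled consensus sequences such as ETS with another direction, 12 lost the call and 4 gained it, without a test of the cause. The thresholds on the peak score, the distances that count as shared between Ba/F3 and HPC7, and the windows for scores at gene lists were not run, since the list gives neither score nor line. The number of libraries, 1 per line and target, and the unknown depth limit all of these values.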

Other observations

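The tests of pseudogene reads, of very active promoters, of purine runs, of chromosome totals without the repeat groups and of peak numbers were chosen after the results they bear on had been seen. The repeat groups were found in these data, and their tests were set down before the tested values were computed. Besides the ribosomal protein list, summits close to a TSS fell at genes of several kinds. The examples here were picked after the values were seen, and no shared function was tested. Gnb2l1, which encodes a protein of the small ribosomal subunit and was not in the fixed list, had a summit 65 bp downstream of its TSS on chromosome 11. Eif4g3, a translation initiation factor gene, had one at 91 bp on chromosome 4, Serbp1, an mRNA-binding protein gene, at 124 bp on chromosome 6, and Snrpb, a splicing protein gene, at 112 bp on chromosome 2. At similar distances lay summits of Ino80d (26 bp), Ywhae (59 bp), Cacng2 (100 bp) and Csnk1d (107 bp), none of them a translation or splicing gene. Of 74 summits within 250 bp of a protein-coding TSS, 39 belonged to the ribosomal protein list (52.7%, interval 40.7% to 64.4%).

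Among the 564 summits outside the repeat groups, chromosome 17 held 54, 2.67 times the number expected from its length (adjusted exact binomial p = 2.77e-09), and chromosome 2 held 70, or 1.81 times (adjusted exact binomial p = 1.61e-05). Chromosome X held 9, or 0.254 times (adjusted exact binomial p = 1.35e-06), whereas 97 summits of the dispersed repeat were on X, 1.66 times the expected number. Here too the expected numbers took no account of assembly gaps or of chromosome copy number in the lines. Of the 461 summits outside both the repeat groups and promoters, 227 (49.2%, interval 44.6% to 53.9%) had an unbroken run of purines or of pyrimidines of at least 40 bp within 100 bp, against 12 of 461 random places (2.60%, Fisher's exact test, adjusted p = 4.38e-67). At ribosomal protein promoters the count of such runs was 0 of 40. Of the 461 summits, 164 lay near a perfect tandem array, so this group is not free of simple repeats. How many of the runs lie in such arrays was not counted.

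The running number in the peak names rose with the distance to the nearest TSS: Spearman's rho was 0.704 and Pearson's r 0.576 across the 2099 summits (permutation p = 1e-05 for rho, the smallest that 100000 permutations can give). Summits are not independent replicates. Of the summits numbered 1 to 100, 98 lay within 1 kb of a TSS, against 49 of the other 1999.

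The enrichment at ribosomal protein promoters was set against 3 technical explanations. Against other genes with CpG-rich promoters the odds ratio was 192 (Fisher's exact test, adjusted p = 1.32e-61), which argues against CpG-rich promoters in general as the whole source. Of the 40 summits, 95% lay in unique windows, which argues against reads shared with processed pseudogenes. Among translation factors, which include some abundantly transcribed genes, 7.69% had a summit, with an upper bound of 20.9% below the lower bound of 39.7% for ribosomal protein genes, and 0 of 50 housekeeping genes listed after the result was known had one. Transcription was not measured in the data analysed here, so a link to the most active promoters of all is weakened by these lists and not removed.

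Of 2 explanations for the summits at AAAGG arrays, tandem arrays of any unit as a source is argued against by the other units, of which AAGGG had the highest share, 5.02%, with no upper bound above 6.71% against a lower bound of 20.5% for AAAGG. Reads collected from many copies went with the pattern: the median copy number was 116.5 at arrays with a summit and 15 without, a difference of 101.5 (one-sided permutation p = 1e-05, the smallest that 100000 permutations can give). Longer arrays have more copies, and within 4 length classes this difference was called in 1, from 60 to 79 bp (28 against 8 copies, adjusted permutation p = 0.028). It was 94 against 49 from 80 to 99 bp and went the other way from 40 to 59 bp (5 against 5.5) and from 100 to 149 bp (19280 against 24760), while 59.4% of the summits of this group lay in unique windows. Binding of the tagged protein or of the antibody to AAAGG, and misplaced reads, thus both stay open, and no biological explanation was tested, since the list does not separate the lines.

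The summits at the dispersed repeat were set against 3 explanations. The share of copies with a summit was 83.7 percentage points higher with 4 or more units than with 1 unit (Fisher's exact test, p = 2.44e-213). The unit was itself read from the summit sequences, and a copy with more units spans more bases. This difference therefore cannot decide whether the summits follow the unit. Copies with a summit also had the higher copy number, 350 against 171, a difference of 179 (one-sided permutation p = 1e-05, the smallest possible), but with 2 units it was 159 against 248 and with 3 units 340 against 298, and among these classes it was called with 4 or more units alone (357 against 302, adjusted permutation p = 0.0217). In 100% of the 291 pairs 2000 to 3000 bp apart both units were on the same strand, against 50.4% of 248 neighbours over 100000 bp apart, which is consistent with pairs that mark both ends of 1 inserted element. Of these 932 summits, 6 lay in unique windows, so collected reads stay open as a source, and no biological explanation was tested.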
